A study of Homo sapiens with 16 samples.

How the data were processed

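Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in MCF7 cells, a human breast cancer line that expresses the estrogen receptor (ER), and in tumours grown from MCF7 cells in mice. The series holds 16 samples. Peak lists of 15 libraries were analysed, and the input DNA sample was not analysed here. Each list gives 5 columns per peak, namely the chromosome, start, end, name and score. Per the submitters' processing notes, reads were aligned with BWA (versions 0.5.5 and 0.6.1-r104 are named, without saying which was used for which library) to hg18, and peaks were called with MACS, whose version is not given in the sources used here. Peaks were deposited per library, not on pooled replicates. Per the file headers, the peaks of 10 lists were called by MACS against a control library, the same for all 10, and the lists of COT2, KLF4, RXRA, TLE3 and IgG have no header line. Whether these 5 were called the same way is therefore not known, and their handling cannot be separated from the factor profiled.

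The score of each peak is the value deposited by the authors in column 5. No list holds a score under 50, which on the log scale of p-values that MACS commonly uses would be a p of 1e-05, although the files do not name the scale. The score was used only to rank, filter or group peaks within a list. The build was checked against chromosome lengths: 0 peaks ran past a chromosome end of hg18, and 1480 ran past an end of hg19. The lists give no read counts, so the sequencing depth of each library is unknown, and the number of peaks cannot be separated from depth or from the yield of the immunoprecipitation.

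Libraries were grouped by factor, drug and cell source from their titles. ER, GREB1 without drug and GREB1 with ICI 182780 had 2 libraries each, and the other groups had 1. For groups with 2 libraries, overlapping peaks were merged and a region was kept if both libraries had a peak in it, and its score was the lower of the 2 highest scores. An overlap was any shared stretch of at least 1 bp. The share of regions with an overlap was given with an exact (Clopper-Pearson) 95% interval. It was tested against 1000 random circular shifts of the regions along each chromosome, two-sided, with a threshold of 0.05 and Benjamini-Hochberg adjustment over 13 tests. The smallest p that these shifts allow is 0.001998. Peak numbers of 2 against 2 libraries were compared with an exact permutation test, which cannot give a p under 0.333. Loss of GREB1 regions by ER overlap was tested with Fisher's exact test, and odds ratios at equal score were Mantel-Haenszel estimates over 5 strata of GREB1 score or 10 strata of ER score. Intervals cover counting error only. Regions are not biological replicates, and the labels do not say whether replicate libraries came from separate cultures, so p-values describe these libraries only.

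Regions were named by a rule set before the data were examined: the 3 with the highest score in each list or set, and the 5 ER regions overlapped by the most other factors, with ties settled by ER score and then by position. Coordinates are 1-based hg18 positions. The gene table used here was of another build, so no gene was assigned to a region. Alternatives set before the data were examined were a score of at least 100, an overlap of at least 50% of the smaller region, peaks of equal width (200 bp either side of the middle), equal numbers of peaks, removal of peaks overlapping IgG, removal of chromosomes 1, 17 and 20, a peak in either library, each replicate left out, same-numbered libraries as a block, and strata of score.

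Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and numba 0.67.0, and figures used matplotlib 3.10.9. The overlap test was checked on simulated lists of equal-width regions placed at random along the chromosomes, so the check does not cover lists whose peaks cluster. Planted shares of 5%, 30% and 95% among about 8000 regions were recovered as 6.51%, 31.6% and 95.2%, and 5 of 100 independent lists of 2000 regions were called at the threshold. A planted odds ratio of 2 among 8000 regions was estimated as 2.27.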

Results

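Genomic binding of ER, of GREB1, a protein encoded by an estrogen-induced gene, and of E2F4, a transcription factor of cell cycle genes, was profiled by ChIP-seq in MCF7 cells and in MCF7 xenograft tumours. ER was profiled in 2 libraries of untreated cells, which held 73968 and 49045 peaks. GREB1 was profiled in 2 untreated libraries, with 16050 and 13696 peaks, and in 2 libraries of cells given 100 nM ICI 182780 (fulvestrant, an ER antagonist that leads to degradation of the receptor) for 4 h, with 7524 and 8250 peaks. One xenograft library each of ER and GREB1 held 49014 and 5176 peaks, and the xenograft GREB1 library used another antibody than the cell line libraries. E2F4 was profiled after 48 h of 100 nM tamoxifen, a selective ER modulator, or 100 nM ICI, with 7765 and 2941 peaks. Single libraries of untreated cells covered COT2 (132451 peaks), the Krüppel-like factor KLF4 (30062), the retinoid X receptor RXRA (20442) and the corepressor TLE3 (20955). Non-specific IgG gave 1356 peaks, none with a score above 175.03. Sequencing depth is unknown for every library. Groups with 1 library have no replicate check.

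GREB1 regions shared by both untreated libraries were found almost entirely where ER was found. Of the 8236 GREB1 regions shared by both untreated libraries, 7828 (95.05%, interval 94.6% to 95.5%) overlapped at least 1 of the 44629 ER regions. Randomly shifted regions did so in 2.64% of cases, a 36.0-fold difference (permutation by shifts, p = 0.001998, the smallest they allow, adjusted p = 0.001998), and IgG peaks did so in 1.77%. In single GREB1 libraries, where weaker peaks seen only once are included, the share was 80.4% ± 1.95 (SD, n = 2). It was 82.4% with peaks of either library for both factors, and 72.6% with equal numbers of the highest-scoring peaks. The strongest GREB1 regions lay on chromosome 2 (11555869 to 11556783, score 3100), chromosome 21 (15503516 to 15505160, score 3100) and chromosome 17 (35858120 to 35859121, score 2622). Each of these 3 regions was also bound by ER, COT2, KLF4, RXRA and TLE3 in untreated cells, and by ER and GREB1 in the xenograft. Random draws from all regions of the series overlapped ER in 19.1% of cases, and GREB1 regions exceeded this 4.98-fold.

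**Figure D1:**
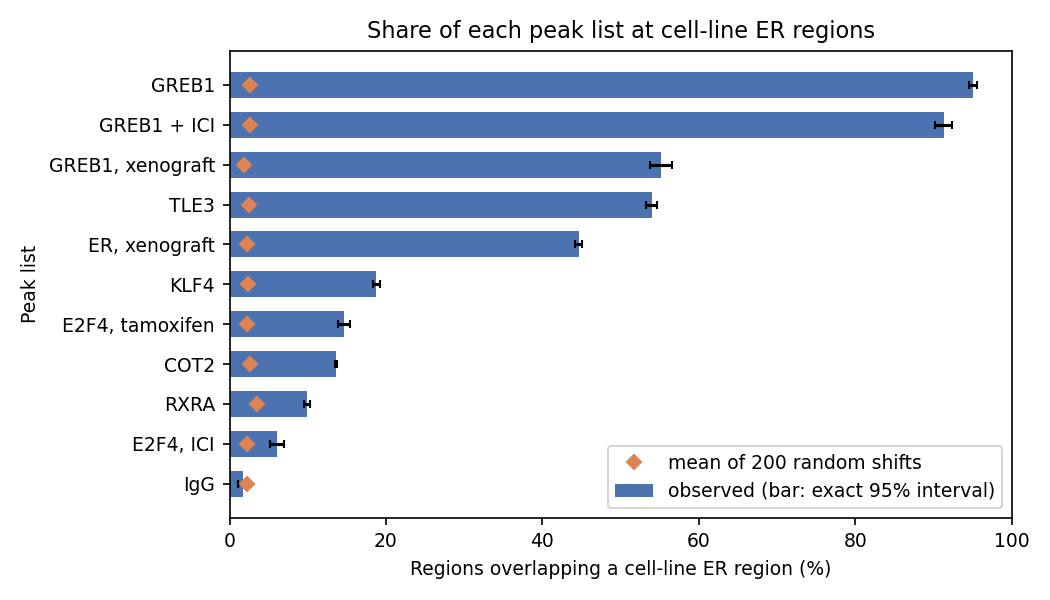
Bars give the percentage of regions of each peak list that overlapped a cell-line ER region, with exact 95% intervals, and diamonds give the mean of 200 random shifts. GREB1 regions reached 95.05% and TLE3 peaks 54.0%, while IgG peaks, at 1.77%, lay close to their shifts.

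The reverse share was much smaller and followed the strength of ER binding. GREB1 covered 7820 of the ER regions, or 17.5% (17.2% to 17.9%), against 0.493% for shifted regions (permutation p = 0.001998). When ER regions were divided into 10 equal classes by ER score, 79.6% carried GREB1 in class 1, with the highest scores, 38.6% in class 2 and 1.64% in class 10. The share was 13.7% ± 3.42 (SD, n = 2) over single ER libraries. It was 49.9% when equal numbers of the highest-scoring peaks were compared, 11.3% with ER replicate 1 alone and 29.2% with GREB1 replicate 1 alone.

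ER regions with GREB1 carried other factors more often than ER regions without it. TLE3 was present at 60.8% of the ER regions with GREB1 and at 17.9% of those without, COT2 at 74.0% and 31.3%, KLF4 at 31.5% and 7.94%, and RXRA at 14.6% and 2.70%. ER regions with GREB1 had higher ER scores, with a median of 882 against 121. Within 10 strata of ER score the odds ratios were lower for TLE3 (3.15, interval 2.95 to 3.36), COT2 (3.27, 3.06 to 3.49) and RXRA (2.97, 2.61 to 3.38) than their unstratified values of 7.12, 6.24 and 6.16, and the ratio for KLF4 was 5.16 (4.76 to 5.61).

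Over all ER regions, COT2 was present at 38.8% (5.34-fold over shifts), TLE3 at 25.4% (21.1-fold), KLF4 at 12.1% (7.68-fold) and RXRA at 4.79% (2.91-fold), each with a permutation p = 0.001998, the smallest the shifts allow. Counted from the peaks of these 4 factors, TLE3 lay at ER regions most often, with 54.0% of its peaks there and 98.4% in the highest of 10 score classes. The corresponding shares were 18.7% for KLF4, 13.6% for COT2 and 9.90% for RXRA. Random draws from all regions of the series, ER regions among them, overlapped ER in 19.1% of cases. Of these 4 factors only TLE3 lay above that level. The folds over shifts therefore do not show that KLF4, COT2 or RXRA preferred ER regions to other regions of the series. The RXRA list also shared regions with IgG, since 8.19% of IgG peaks overlapped an RXRA peak, 4.70-fold over shifts, against 1.77% that overlapped an ER region. Depending on the setting, the RXRA share moved to 2.72% at scores of at least 100 and 8.85% at equal numbers of peaks, and the TLE3 share to 16.7% with ER peaks of either library and 44.5% at equal numbers.

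**Figure D2:**
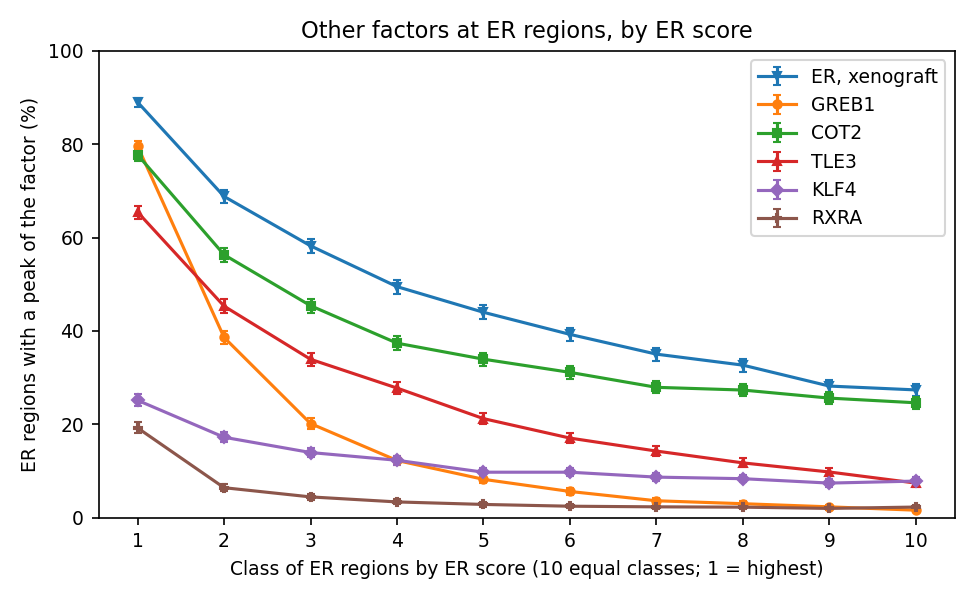
The percentage of ER regions with a peak of each factor (vertical axis, exact 95% intervals) is plotted for 10 equal classes of ER regions from the highest to the lowest ER score (horizontal axis). GREB1 went from 79.6% to 1.64%, TLE3 from 65.4% to 7.44% and xenograft ER from 89.0% to 27.4%.

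Some ER regions carried several of the other factors. At least 3 of GREB1, COT2, KLF4, RXRA and TLE3 were present at 5763 ER regions, 12.9% of the total, where independent shifts of each factor gave 0.0119% (permutation p = 0.001998). Such shifts also take away each factor's own overlap with ER, so they do not show whether the factors lay together beyond those overlaps. With each factor permuted among the ER regions, a comparison chosen after seeing the data, chance gave 4.57%, and within 10 strata of ER score 9.29%, a 1.39-fold difference (permutation p = 0.00995, the smallest these rounds allow). All 5 were present at 492 regions, whose median ER score was 2247, and none at 21113 regions, whose median ER score was 105. The 5 regions ranked first lay on chromosome 14 (63214006 to 63215075, ER score 3154) and chromosome 1 (998232 to 999980, 42027508 to 42028789, 109583486 to 109586068 and 111856889 to 111858457, each with a score of 3100). A score of 3100 was shared by 957 ER regions, so position decided among the last 4. The second-ranked ER region by score, on chromosome 5 (82894570 to 82895895, score 3110), carried GREB1, COT2 and TLE3.

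**Figure D3:**
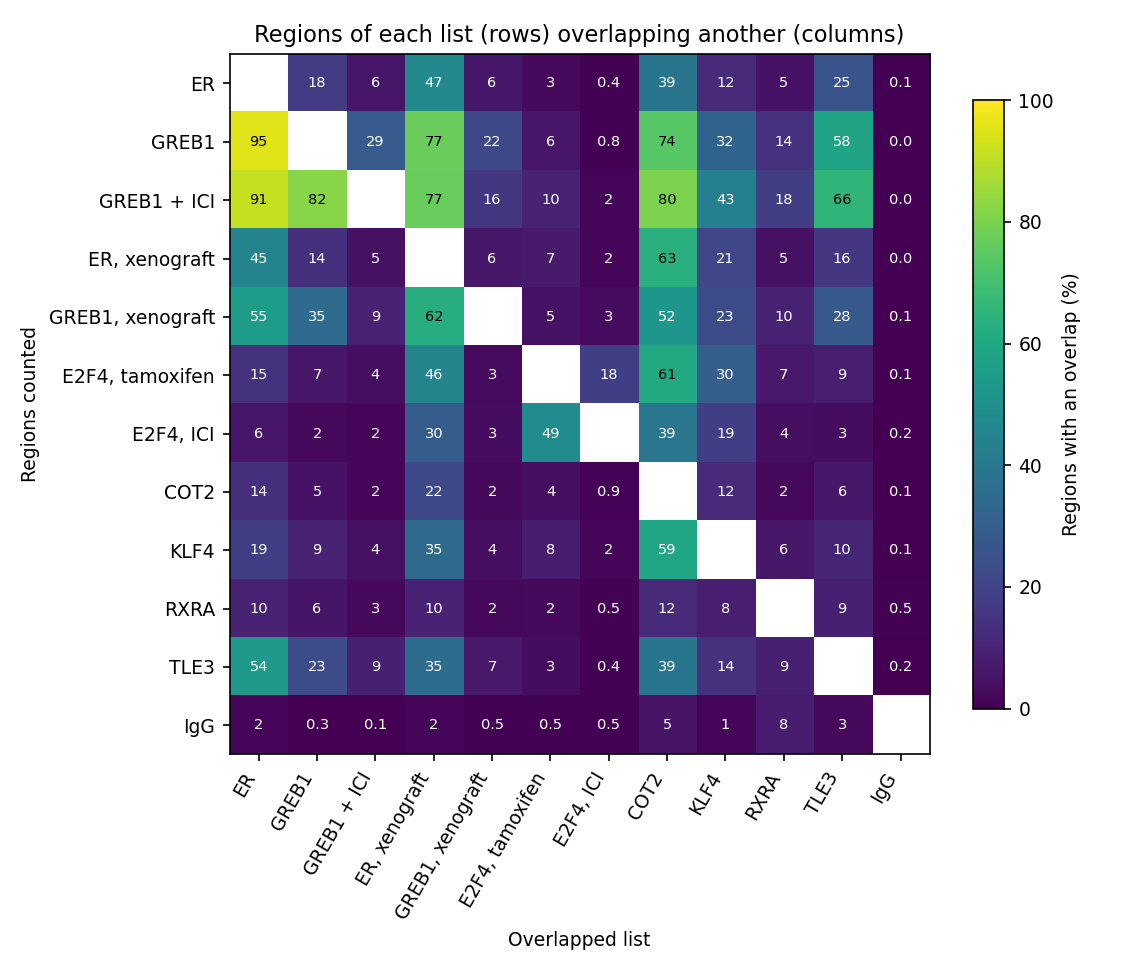
Each cell gives the percentage of regions of the list in its row that overlapped the list in its column, coloured from 0% to 100%. GREB1 overlapped cell-line ER (95.05%), KLF4 overlapped COT2 (58.8%) and E2F4 after tamoxifen overlapped COT2 (60.6%), while the IgG column stays at 0.548% or less.

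ICI for 4 h was compared with no drug to see what an ER antagonist does to GREB1 binding. GREB1 peak numbers were 14873 ± 1665 without drug and 7887 ± 513 with ICI (SD, n = 2 each), 53.0% of the untreated number or a log2 change of -0.92. Both ICI libraries lay below both untreated libraries, although the exact permutation p of 0.333 is the smallest that 2 against 2 libraries allow. At scores of at least 100 the log2 change was -1.70. The share of peaks at ER regions was 80.4% ± 1.95 without drug and 60.6% ± 8.37 with ICI, with the same permutation p of 0.333. Fewer ICI peaks scored at least 100, 23.7% and 23.3% against 43.6% and 37.0% without drug. Peaks of ICI replicate 2 were also narrower, with a median of 202 bp against 707 and 495 bp without drug. The lower share at ER was not separated from these differences. Of the 8236 untreated GREB1 regions, 4484 (54.4%, 53.4% to 55.5%) had a peak in either ICI library, 83.2-fold over shifts (permutation p = 0.001998), and 28.6% had one in both. The share kept was 31.9% for GREB1 peaks of either untreated library and 36.0% with GREB1 replicate 2 alone. Peaks also failed to recur within a condition. Without drug, 51.5% of replicate 1 peaks and 61.5% of replicate 2 peaks were found in the other library, and with ICI 38.0% and 36.5%. No further untreated library gives the share of the 8236 regions that would be kept without drug, so absence after ICI is not all loss to the drug.

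GREB1 regions found after ICI were compared with ER regions, which were mapped in untreated cells only. Of the 2858 regions found in both ICI libraries, 91.3% overlapped such an ER region and 82.4% an untreated GREB1 region, and 70 overlapped no untreated GREB1 peak. Of the 12759 regions found in either ICI library, 53.1% (52.3% to 54.0%) overlapped an ER region, and the single ICI libraries gave 66.5% and 54.7%. The 3 strongest GREB1 regions named above, on chromosomes 2, 21 and 17, all kept a peak in both ICI libraries. The highest-scoring regions among those without a peak in either ICI library lay on chromosome 1 (7430241 to 7431103, score 1881), chromosome 2 (11589780 to 11590654, score 1865) and chromosome 5 (117372953 to 117374060, score 1680), all at ER regions. In the ICI libraries themselves the strongest shared regions lay on chromosome 10 (7315055 to 7316144), chromosome 3 (193797748 to 193798870) and chromosome 1 (117611622 to 117613675).

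Loss of GREB1 regions at ER and elsewhere was compared on regions of both untreated libraries, where lost means no peak in either ICI library. Without ER means no overlap with an ER region of both ER libraries. Of the 408 such GREB1 regions, 259 (63.5%) overlapped an ER peak of at least 1 ER library, so most were not free of ER. Of 7828 regions with ER 46.2% (45.1% to 47.3%) were lost, and of 408 without ER 32.6% (28.1% to 37.4%), an odds ratio of 1.78 (1.43 to 2.21, Fisher's exact test, two-sided, p = 5.6e-08). Against ICI replicate 1 alone the difference missed the threshold, with 57.6% and 52.9% lost (odds ratio 1.21, 0.983 to 1.48, Fisher's exact p = 0.0722), and against ICI replicate 2 alone the odds ratio was 1.76 (1.43 to 2.16). Within 5 strata of GREB1 score the odds ratio was 2.59 (2.07 to 3.24). In the stratum with the highest scores 31.1% of 1629 regions with ER were lost and 0 of 18 without ER, which allows up to 18.5% (exact interval), and in the stratum with the lowest scores 63.1% of 1498 and 75 of 150. The direction turned when all peaks of a single untreated library were counted, with an odds ratio of 0.372 for replicate 1 and 0.225 for replicate 2. With loss counted against the ICI library of the same number instead, peaks of replicate 1 at ER were lost in 65.7% of cases and the others in 84.5% (odds ratio 0.352), and those of replicate 2 in 69.7% and 89.3% (odds ratio 0.275). Of these last peaks, the highest of 5 score classes had 33.4% of 3149 with ER against 4.92% of 61 without ER lost in replicate 1 and 49.7% of 2688 against 15.7% of 51 in replicate 2, while the lowest class had 90.4% against 94.8% (odds ratio 0.516) and 85.5% against 96.5% (odds ratio 0.217). Over all 5 classes the odds ratios at equal score were 0.992 (0.877 to 1.12) and 0.627 (0.547 to 0.718). Single-library peaks without ER often failed to recur without drug too. In replicates 1 and 2, 86.1% and 85.6% of them were absent from the other untreated library, against 40.1% and 26.0% of those with ER. Odds ratios under 1 for such peaks therefore do not show less loss at ER after ICI.

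**Figure D4:**
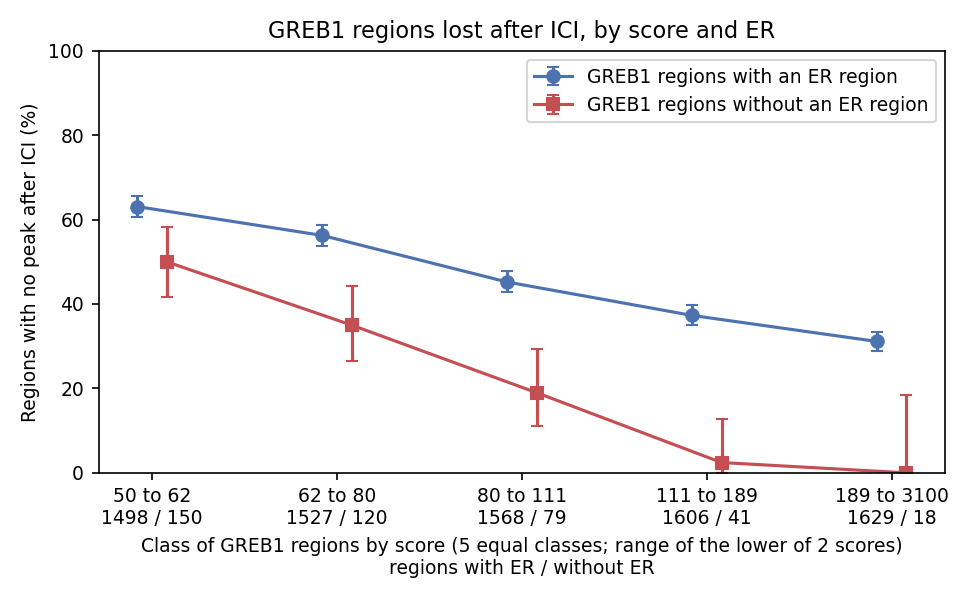
The percentage of GREB1 regions of both untreated libraries with no peak in either ICI library (vertical axis, exact 95% intervals) is plotted for 5 equal classes of GREB1 score (horizontal axis, with the number of regions with and without ER). Regions with ER went from 63.1% to 31.1% lost, and regions without ER from 75 of 150 to 0 of 18. Without ER means no ER region of both ER libraries, and 63.5% of these 408 regions overlapped an ER peak of at least 1 library.

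Lost and kept GREB1 regions differed in the other factors present. Over all regions, lost ones had KLF4 less often than kept ones (22.1% against 40.7%), and the same held for E2F4 after tamoxifen (3.28% against 8.54%), COT2 (67.6% against 79.5%) and TLE3 (50.3% against 65.0%). At equal GREB1 score the odds ratios were 0.461 (0.417 to 0.509) for KLF4, 0.400 (0.323 to 0.496) for E2F4, 0.684 (0.616 to 0.760) for COT2 and 0.682 (0.621 to 0.749) for TLE3. Lost regions had a xenograft GREB1 peak more often, 27.9% against 16.2%, an odds ratio of 1.99 (1.79 to 2.22) over all regions and 3.87 (3.40 to 4.40) at equal score.

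The xenograft libraries show where ER and GREB1 lie in tumours grown from the same line. Of the 5176 xenograft GREB1 peaks, 3234 (62.5%, 61.1% to 63.8%) overlapped a xenograft ER peak, 35.5-fold over shifts (permutation p = 0.001998), against 1.55% of IgG peaks. Over 10 equal classes of GREB1 score the share was 99.8% in class 1, 69.8% in class 5 and 28.8% in class 10, and 97.8% at scores of at least 100. The 3 strongest xenograft GREB1 peaks lay on chromosome 19 (1132584 to 1133275), chromosome 9 (129828787 to 129829441) and chromosome 17 (35858300 to 35858918), all overlapping ER and GREB1 regions of cultured cells. The chromosome 17 peak lies inside the third-ranked GREB1 region of cultured cells.

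Cultured cells and tumours shared part of their binding. Of 49014 xenograft ER peaks, 44.6% (44.2% to 45.1%) overlapped a cell-line ER region, 20.2-fold over shifts, and the share went from 89.5% in the highest of 10 score classes to 23.4% in the lowest. Of the xenograft GREB1 peaks, 35.0% (33.7% to 36.4%) overlapped a cell-line GREB1 region, 95.01-fold over shifts, although the antibodies differed, and 90.3% did in the highest of 10 score classes (each permutation p = 0.001998). The highest-scoring xenograft ER peaks, 4 with a tied score of 3233, included regions on chromosome 2 (72655481 to 72656188), chromosome 8 (142401431 to 142402401) and chromosome 11 (74424475 to 74425244). All 3 overlapped cell-line ER regions. At scores of at least 100, the share of xenograft GREB1 peaks with a cell-line GREB1 region was 53.9%.

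For E2F4 the 2 ER-directed drugs were compared at the same dose and time, with no untreated E2F4 library analysed. The tamoxifen library held 2.64 times as many peaks as the ICI library (counting interval 2.53 to 2.76), which without replicates compares 2 libraries and not the drugs. Of the ICI peaks 48.7% (46.9% to 50.5%) overlapped a tamoxifen peak, 129-fold over shifts (permutation p = 0.001998), and at scores of at least 100 the share was 93.1%. Over 10 equal classes of tamoxifen peaks by score, 98.1% had an ICI peak in class 1, 51.4% in class 2 and 0.644% in class 10. The strongest tamoxifen peaks, on chromosome 3 (101018347 to 101020049), chromosome 11 (95162307 to 95163504) and chromosome 1 (245161654 to 245162483), were all present after ICI and lay outside ER regions of cultured cells. The strongest ICI peaks lay on chromosome 8 (124477600 to 124478623) and chromosome 19 (51122689 to 51123471), followed by a block of 33599 bp on chromosome 21 (9800591 to 9834189) that also overlapped peaks of the GREB1 libraries with ICI and from the xenograft. The median width in that E2F4 library was 496 bp. The block overlapped no region of ER, untreated GREB1, COT2, KLF4, RXRA or TLE3. No filter for artefact-prone regions was applied, so it may not be a binding site.

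E2F4 peaks overlapped cell-line ER regions less often than GREB1 peaks of single untreated libraries did (80.4% ± 1.95, SD, n = 2). ER was mapped in untreated cells only, while E2F4 was mapped after 48 h of tamoxifen or ICI, so drug and factor were not separated. Of the E2F4 tamoxifen peaks 14.7% (13.9% to 15.5%) overlapped an ER region, 6.39-fold over shifts (permutation p = 0.001998), against 1.77% of IgG peaks, and 6.05% of the ICI peaks did. Both E2F4 shares lay below the 19.1% of random draws from all regions of the series. COT2 was present at 60.6% and KLF4 at 30.2% of the tamoxifen peaks, and xenograft ER at 45.6%. The overlap with ER depended on the ER list: it was 31.4% with ER replicate 1 alone, 15.0% with replicate 2 alone, 32.1% with peaks of either and 9.30% at scores of at least 100.

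The strongest peaks of the remaining factors divided by their neighbours. The first-ranked TLE3 peaks, on chromosome 21 (15504215 to 15505148), chromosome 20 (54766633 to 54768158) and chromosome 3 (178055920 to 178057178), all overlapped ER and GREB1 regions. The first-ranked RXRA peak (chromosome 12, 92487546 to 92490720) overlapped no cell-line ER region, while the next 2, on chromosome 16 (73620493 to 73622409) and chromosome 15 (72624802 to 72626680), overlapped ER and the other 4 factors. The KLF4 peaks on chromosome 9 (72222603 to 72225752) and chromosome 20 (60246187 to 60247128) overlapped ER and GREB1, and the one on chromosome 4 (76774155 to 76775340) overlapped COT2 and xenograft ER only. Of the COT2 peaks, 7 with a tied score of 3233, the first by position on chromosome 7 (1537137 to 1541605) overlapped ER, and those on chromosome 8 (124801336 to 124802132) and chromosome 9 (138497820 to 138500857) did not overlap cell-line ER. The strongest IgG peak lay on chromosome 10 (46478389 to 46479929), and the next, on chromosome 21 (40279097 to 40280190), overlapped ER in cells and xenograft. The third-ranked IgG peak, on chromosome 7 (131982004 to 131983697), overlapped an RXRA peak.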

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

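The odds ratios in this part, and the tests of explanations except where stated, were chosen after the results had been seen. GREB1 met ER more often in cultured cells than in the xenograft, 95.05% of regions against 62.5% of peaks, and the difference between the sources was tested as an odds ratio of 11.5 (10.3 to 12.9). The cultured regions had to be present in 2 libraries, and in single culture libraries the share was 80.4% ± 1.95. At scores of at least 100 the difference was gone, with 96.9% (96.3% to 97.4%) in culture and 97.8% (97.0% to 98.5%) in the xenograft. It was still seen in other settings, which do not compare the sources evenly. With equal numbers of the highest-scoring peaks, set within each source, the shares were 72.6% (71.6% to 73.6%) and 52.4% (51.0% to 53.7%). At equal width they were 91.9% and 58.6%. The equal number differed between the sources, and in both settings the cultured regions still had to be present in 2 libraries. The xenograft peaks needed only 1, and their share fell from 99.8% to 28.8% between the highest and lowest of 10 classes of GREB1 score. The xenograft is 1 library made with another antibody, so source, antibody and low-scoring peaks seen in a single library were not separated.

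E2F4 peaks after tamoxifen met ER more often when ER was taken from the xenograft, 45.6% against 14.7% for the cell-line regions, an odds ratio of 4.87 (4.51 to 5.27), whose interval treats the shares as independent although both are of the same 7765 peaks. Of these, 2663 overlapped ER of the xenograft and not of the cell-line regions and 264 the reverse, a ratio of 10.1 (8.89 to 11.5). ER replicate 1, the nearer culture library, gave 31.4%. The tumour ER list was the shortest and covered the least. It covered 30.6 Mb with 49014 peaks, against 43.9 Mb with 73968 and 37.5 Mb with 49045 in culture. These values argue against a longer list or wider peaks as the source. With 49014 peaks of equal width from each list the tumour share was 41.6% against 19.4%, a ratio of 2.15. That cut in number removed peaks from the culture lists only, so it does not test list length. A test written before this result was seen used only the 5176 highest-scoring peaks of each list. It gave a ratio of 0.902, so the tumour share was no higher there, but it leaves out the lower-scoring peaks that hold the excess. Peaks near the authors' threshold held part of the excess but not all of it. Over 10 equal classes of ER peaks by score the ratio was 1.40 in class 10, with the lowest scores. It was 3.33 in class 5 (9.73% of tumour peaks with E2F4 against 2.92%), a class picked after the values had been seen. The test written first, although the tumour share had been seen, used class 1. The ratio there was 1.07 and the intervals overlap, so that test decided nothing. Leaving out chromosomes 1, 17 and 20, parts of which are gained in MCF7, left a ratio of 1.44 against 1.45 with all chromosomes, and the bound first written for this test lay above both and so decided nothing. A difference between tumour and culture stays open, as does signal at open chromatin that does not depend on the ER antibody, since there is 1 tumour ER library and no tumour IgG list was analysed.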

How the results depend on the processing

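All 105 alternatives for the shares of overlapping regions stayed above chance at p under the threshold, with folds over chance from 1.39 upward, and all 8 alternatives for the GREB1 peak number kept its direction, with log2 changes from -1.70 to -0.80. Of 133 alternatives in total, 126 gave the same call. Most alternatives for the shares used the random shifts again, a low bar that even IgG peaks at RXRA peaks exceeded 4.70-fold. Passing it does not show that a share is stable. The share of ER regions with GREB1, for example, ranged from 11.3% to 49.9%. The lowest fold was that of ER regions with at least 3 other factors, where each factor was permuted among ER regions within strata of score (9.29% by chance, and 4.57% without strata), 2 alternatives chosen after seeing the data. The ratio of E2F4 peak numbers moved from 2.64 to 3.31 at scores of at least 100. The odds ratio of GREB1 loss by ER (1.78) kept its side of 1 and of the threshold in 12 of 18 alternatives, among them 3.08 at scores of at least 100 and 2.59 in strata of score, but 1.30 (1.10 to 1.53) at equal width and 1.25 (1.005 to 1.55) for regions kept in both ICI libraries. It was 0.174 with a peak in either replicate library, and it ranged from 0.225 to 1.94 with each library left out in turn: without GREB1 replicate 1 it was 0.225, without GREB1 replicate 2 it was 0.372, and without GREB1_ICI replicate 2 it was 1.21 with Fisher's exact p = 0.0722. These alternatives count peaks seen in 1 untreated library, or 1 ICI library, and of the peaks away from ER in untreated replicates 1 and 2, 84.5% and 89.3% had no peak in the same-numbered ICI library. Of the same peaks, 86.1% and 85.6% had no peak in the other untreated library, against 40.1% and 26.0% of peaks with ER. Odds ratios under 1 for single-library peaks therefore do not show that ICI spared GREB1 at ER. Why these peaks did not recur was not tested. With same-numbered libraries as a replicate block the odds ratio was 0.316, the share kept 28.5% and the log2 change in peak number -0.91. The numbers are not known to pair the libraries: with only 2 pairs, the differences between replicates correlated at 0.205 over 2354 regions. Chosen after seeing the data, a replicate block with strata of score gave 0.802, the same on regions of both untreated libraries gave 2.23, and ER peaks of either library with strata of score gave 3.20. Unknown depth limits every count of peaks and every statement that a region has no peak.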

Other observations

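The tests in this part were chosen after the results had been seen. ER regions listed in the tumour and not in the regions of both culture libraries, or the reverse, differed in their neighbours. Of the 27135 xenograft ER peaks without a cell-line ER region, 10519 (38.8%) overlapped an ER peak of at least 1 culture library, and 67.5% had COT2, 22.0% KLF4 and 9.87% E2F4 after tamoxifen, and 2.34% had TLE3 and 1.22% GREB1. Of the 23557 cell-line ER regions without a xenograft ER peak, 21.0% had COT2, 4.27% KLF4 and 1.09% E2F4, and 4476 of them had TLE3 and 7.46% GREB1. Among the 21879 xenograft ER peaks shared with cells, 58.1% had COT2, 20.3% KLF4, 4.12% E2F4 after tamoxifen, 32.3% TLE3 and 28.7% GREB1. KLF4 was thus about as frequent at shared xenograft ER peaks as at those without a cell-line ER region. Chromosome 19 held 5.15% of xenograft ER peaks, 5.32% of E2F4 tamoxifen peaks, 5.29% of COT2 peaks and 5.35% of KLF4 peaks, but 2.41% of cell-line ER regions and 1.91% of TLE3 peaks.

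E2F4 peaks present with both drugs, 1434 of the tamoxifen peaks with a median score of 674, had COT2 at 78.9% and KLF4 at 38.3%. The 6331 seen only after tamoxifen had a median score of 68.3, COT2 at 56.4% and KLF4 at 28.4%. The 1508 seen only after ICI had a median score of 55.6, COT2 at 1.79% and KLF4 at 0.531%. Both shares lay below those of randomly shifted E2F4 ICI peaks, 6.92% for COT2 and 1.48% for KLF4. Xenograft GREB1 peaks divided in a like way: the 3234 at xenograft ER had COT2 at 80.6% and cell-line GREB1 at 56.1%, and the 1942 others had COT2 at 5.30% and cell-line GREB1 at 0.0515%.

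The 408 GREB1 regions without an ER region had E2F4 after tamoxifen at 26.5% against 5.08% of those with ER, KLF4 at 52.9% against 31.2% and TLE3 at 10.0% against 60.8%. Listed IgG peaks do not account for them, since 0 of 408 overlapped one, where the exact interval reaches 0.9001%, though the IgG list was short. ER peaks missed by the requirement for both libraries may account for many: 63.5% (58.6% to 68.2%) overlapped an ER peak of at least 1 library. Signal at open chromatin that does not depend on the GREB1 antibody may account for others, since at equal score they had a xenograft GREB1 peak, made with another antibody, less often than GREB1 regions with ER (odds ratio 0.203, 0.119 to 0.349). A difference between tumour and culture was not separated from that of the antibodies.

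A lower number of GREB1 peaks after ICI could come from fewer reads or a uniformly lower yield. If score alone then decided what is lost, regions of equal score would be lost equally often with and without ER. For regions of both untreated libraries the odds ratio of loss at equal score was 1.80 (1.46 to 2.23) against ICI replicate 1 and 2.77 (2.24 to 3.43) against ICI replicate 2. These values do not decide it, because the regions were picked for a peak in both untreated libraries. In untreated replicates 1 and 2, 86.1% and 85.6% of peaks without ER were absent from the other untreated library, against 40.1% and 26.0% of those with ER. Shared regions without ER were thus a more selected set, with no comparison without drug. For peaks of single untreated libraries the odds ratios over all 5 score classes, 0.992 (0.877 to 1.12) in replicate 1 and 0.627 (0.547 to 0.718) in replicate 2, average classes that go opposite ways. In classes 4 and 5, with the highest scores, the values argue against a uniform loss, with 1.51 (1.13 to 2.02) and 9.68 (3.14 to 48.4) in replicate 1 and 2.05 (1.43 to 2.95) and 5.31 (2.46 to 13.1) in replicate 2, although class 5 held only 61 and 51 peaks without ER. In the same classes, absence from the other untreated library gave odds ratios of at most 0.647. In classes 1 to 3 it stays open: no odds ratio exceeded 1.08 (0.851 to 1.37), and low ones do not count against it, since between the untreated libraries they were lower still (0.217 and 0.116 over all classes). A weaker GREB1 immunoprecipitation cannot be told apart from a loss of GREB1 itself: 57.3% of shared regions were lost even against the ICI library with fewer losses, and no class of sites in these lists separates the 2. A hypothesis is that some kept regions hold signal that does not depend on the GREB1 antibody, as at equal score lost regions had a xenograft GREB1 peak, made with another antibody, more often than kept ones (odds ratio 3.87, 3.40 to 4.40). Displacement of GREB1 by a loss of ER is a hypothesis that was not tested, since ER was mapped in untreated cells only.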
